A study of Arabidopsis thaliana with 12 samples.

How the data were processed

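Per the labels, gene expression was measured by RNA-seq in 12 Arabidopsis thaliana leaf libraries, 3 replicates in each of 4 groups. The groups crossed 2 genotypes, wild type (WT) and the yb2 yb3 double mutant of the transcription factor genes NF-YB2 and NF-YB3, with a mock treatment or infection by the grey mould fungus Botrytis cinerea. Seeds were germinated for 7 d on medium, moved to soil and kept at 22 °C under 16 h of light and 8 h of dark, per the labels' protocols. Per the labels' protocols, 4-week-old plants received a 5 µl droplet, or a spray over the entire plant, of a suspension with 2500000 spores per mL. Which of these methods was used for the sequenced leaves, and the time from inoculation to harvest, were not given in the sources used here. Per the labels' protocols, RNA was taken from 10-d-old seedlings, which differs from the leaves of 4-week-old plants named in the labels' treatment and tissue text, so the age of the sequenced material was uncertain. Nothing in the labels said whether the 3 replicates of a group came from separate plants. If they did not, the p-values measure only the spread between these samples.

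Libraries were sequenced as paired reads of 150 nt on an Illumina NovaSeq instrument, per the labels' protocols. Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 to the TAIR10 build and DESeq2 1.30.1 was used. The authors deposited 1 table per library with a whole-number read count for each of 38189 genes, with the coordinates, strand and length of each gene, per the file headers. The deposited counts were raw: they differed in total between libraries and carried no scaling. The counting program, its strand setting, its treatment of reads with several matches and whether reads or fragments were counted were not given in the sources used here. All 12 tables listed the same genes in the same order. No read was counted for 12794 genes in any library. Reads of the fungus were not in the tables.

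Gene symbols and product descriptions came from the RefSeq annotation of the TAIR10.1 assembly, matched by locus code. Of the gene identifiers, 37971 matched, and 37774 of these had the same start and end in the annotation as in the deposited tables. Coordinates are those of the deposited tables, counted from 1. Total counts per library ran from 10082808 to 20187050, so that 3 counts, taken as the limit that a count of 0 allows, stood for 0.143 to 0.315 CPM, counts scaled to a common library total, on the TMM-scaled library sizes. Such limits and the 95% counting intervals of ratios cover counting error only. The intervals use counts summed over a group and leave out the spread between its libraries. Reads amplified by PCR are not independent molecules either.

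Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as its argument, which left 19009 genes, and libraries were scaled by TMM factors. One model with a term per group was fitted to all 12 libraries by glmQLFit with robust estimation, so that the 4 groups shared 1 estimate of the spread. The 5 contrasts were tested with edgeR's quasi-likelihood test: infected against mock in each genotype, mutant against WT in mock and in infected leaves, and the difference between the infection responses of the genotypes (interaction). A gene was called when its Benjamini-Hochberg adjusted p over the tested genes was under 0.05. Fold changes are log2. Their standard error (SE) was taken as the absolute log2 fold change divided by the square root of the F statistic of the quasi-likelihood test. It restates that test and is no separate measure of spread. CPM values are means ± SD of 3 libraries of a group, computed with the TMM-scaled library sizes. A gene whose libraries of 1 group were all at 0 is given as a bound against 3 counts summed over that group, and a gene with 1 to 3 counts in the lower group as a ratio of summed counts relative to the scaled library sizes, with its exact 95% counting interval.

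The groups, tests, contrasts, gene lists, rule for named genes and first set of alternatives were chosen before the data were examined. The lists held 361 genes in 28 lists, all of them found in the tables, and 348 of the symbols were the same in the annotation. The 21 pathway lists were the NF-Y family, jasmonate biosynthesis, jasmonate catabolism, JAZ repressors, MYC branch of the jasmonate response, ERF branch of the jasmonate and ethylene response, ethylene biosynthesis and signalling, salicylic acid pathway, camalexin and tryptophan pathway, indole glucosinolates, aliphatic glucosinolates, pattern recognition and early immune signalling, WRKY factors, phenylpropanoid and lignin, cell wall and polygalacturonase inhibitors, glutathione transferases and oxidative stress, abscisic acid response, senescence and chlorophyll breakdown, photosynthesis, flowering time, and circadian clock. The others were 6 reference genes and markers of guard cells, vascular tissue, trichomes, shoot meristem, flowers and seeds. Pathway lists were tested with camera of limma 3.58.1, which asks whether the members of a list moved relative to the other genes, with a preset correlation of 0.01 between members and Benjamini-Hochberg adjustment over the 21 lists of a contrast. Beside it stand camera with the correlation estimated from these libraries and fry, which asks whether the members moved in 1 direction on balance without comparing them with other genes. Families of genes picked by words in their product description were an exploratory set with an adjustment of their own.

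Named genes followed a fixed rule. In each contrast these were the 6 largest rises and 6 largest falls among called genes with a symbol, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups (the interaction had no demand on overlap). To these came up to 4 called members of each list with the smallest adjusted p, or at most 2 where a list had under 3 called members and did not pass its test, and in every contrast NF-YB2, NF-YB3, MYC2, ORA59, ERF1, PDF1.2a, PDF1.2b, VSP2, LOX2, PAD3, WRKY33, PR1 and FT. Reference and marker lists are given as counts with the member of highest mean CPM. Marker lists with enough tested genes were also tested with camera, with Benjamini-Hochberg adjustment over the tested marker lists alone. A gene named outside this rule is said to have been chosen after its values were seen. Of the genes taken from the lists, those that best show the direction of a list are printed.

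In the libraries labelled WT infected replicate 3 and yb2 yb3 infected replicate 3, transcripts that marked the genotypes went against the labels. The main comparisons kept every library under its label. A second fit of the other 10 libraries (19417 genes), chosen after the data were examined, is printed beside the main one for comparisons that use infected libraries of both genotypes, and no library was moved to another group. Other alternatives were DESeq2 1.42.0, scaling by library totals or by the RLE factors of edgeR, no filter, a filter of 10 CPM in 3 libraries, a demand of 1 on the absolute log2 fold change, limma voom, a fit of only the compared groups, the replicate number as a block, leaving out genes of the organelles, and leaving out each library.

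The fit was tested on simulated data, in which 200 of 18707 to 19169 genes were changed in each of 3 simulations per contrast. At folds of 1.5, 2 and 4, the 12-library fit recovered 38.3%, 70.6% and 88.9% of them for infection in WT, 41.3%, 68.7% and 86.9% for infection in the mutant, 38.8%, 70.1% and 87.4% between mock groups, 35.3%, 67.2% and 87.9% between infected groups, and 8.5%, 50.7% and 78.3% for the interaction. False calls made up 4.4% to 7.3% of calls. With 10 libraries, recovery was 35.8%, 60.7% and 78.8% between infected groups, 51.7%, 72.1% and 87.9% between mock groups and 14.9%, 45.8% and 76.3% for the interaction, with 8.1% to 9.4% false calls. Lists whose genes were shifted by 0.5 on the log2 scale passed camera in 6 of 6 simulated cases, against 1 of 57 unshifted lists. This was simulated only for the comparison of infected genotypes, with genes drawn independently and no correlation between members of a list. The 1 of 57 is therefore not a false-call rate for lists in the real libraries.

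Where genes overlap on opposite strands, their reads cannot be told apart without a known strand setting. In these tables, 476 of the 487 protein-coding genes with at least 95% of their exon bases shared with another gene had no count in any library (97.7%), against 3949 of the 19861 with no shared base (19.9%). A count of 0 in such a gene was therefore not read as absence of expression. Python 3.11.15 with numpy 2.4.6 prepared the tables and matplotlib 3.10.9 drew the figures. No column of the deposited tables was left unused. Fungal load, disease symptoms and hormone levels were not measured in the tables.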

Results

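RNA-seq counts were obtained from leaves of wild-type (WT) Arabidopsis and of the yb2 yb3 double mutant, which carries mutations in NF-YB2 and NF-YB3. These genes encode subunits of the trimeric NF-Y factor, which binds CCAAT boxes in promoters and is known for its part in flowering. The series asked how the pair acts in jasmonate signalling and in resistance to Botrytis cinerea, a fungus that kills leaf tissue and feeds on it. Each of the 4 groups held 3 libraries. Total counts in WT mock replicates 1, 2 and 3 were 17943361, 18350556 and 20187050, and in yb2 yb3 mock replicates 1, 2 and 3 they were 19869806, 19373353 and 18276701. In the libraries labelled WT infected replicates 1, 2 and 3 the totals were 15343761, 13773080 and 10248535, and in those labelled yb2 yb3 infected replicates 1, 2 and 3 they were 10082808, 10752367 and 14881507. The 10 most abundant genes took 12.9% to 14.4% of the counts in mock libraries and 5.45% to 6.02% in infected ones. The first principal component of log2 CPM held 92.3% of the variance and separated the mock libraries, at scores of -152.16 to -138.87, from the infected ones, at 119.34 to 172.02.

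NF-YB2 (AT5G47640, TAIR10 chromosome 5, 19309227 to 19310272, plus strand) had 186, 220 and 199 counts in WT mock replicates 1, 2 and 3, and 1, 12 and 5 in the yb2 yb3 mock replicates. In infected leaves it had 65 and 38 counts in WT replicates 1 and 2 but 1 in the library labelled WT infected replicate 3. The yb2 yb3 infected replicates 1 and 2 held 0 and 5 counts of NF-YB2, while the library labelled yb2 yb3 infected replicate 3 held 29. NF-YB3 (AT4G14540, chromosome 4, 8344349 to 8345324, plus strand) was still counted in the mutant, with 289, 287 and 254 counts in its mock replicates against 443, 496 and 652 in those of WT. In infected leaves NF-YB3 had 59, 60 and 18 counts in the libraries labelled WT replicates 1, 2 and 3, and 12, 26 and 36 in those labelled yb2 yb3. The last of these, at 2.38 CPM, was near yb2 yb3 infected replicate 2, at 2.46 CPM, and below WT infected replicates 1 and 2, at 3.77 and 4.27 CPM. The labels gave neither the place nor the kind of the mutations, so reads from an unaffected part of NF-YB3 cannot be told from intact transcript.

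Other transcripts that separated the mock genotypes went against the same labels; they were chosen after their values were seen. The long non-coding RNA AT3G06955 had 638, 603 and 585 counts in the mutant mock libraries and 1, 0 and 0 in those of WT. It had 341 counts in the library labelled WT infected replicate 3, against 0 and 3 in the other WT infected libraries, and 1 count in the library labelled yb2 yb3 infected replicate 3, against 259 and 308 in the other infected mutant libraries. MAF5, a relative of the flowering repressor FLC, had 310, 229 and 342 counts in WT mock and 24, 29 and 38 in mutant mock libraries. The libraries labelled WT infected replicate 3 and yb2 yb3 infected replicate 3 held 20 and 244 counts of MAF5, where the other infected libraries held 246 and 273 in WT and 21 and 5 in the mutant. HB-7 (AT2G46680), a homeobox gene induced by drought, had 79, 76 and 91 counts in WT mock and 33, 37 and 30 in mutant mock libraries. It had 396 and 397 counts in WT infected replicates 1 and 2, 1 and 4 counts in yb2 yb3 infected replicates 1 and 2, 1 count in the library labelled WT infected replicate 3 and 387 in the one labelled yb2 yb3 infected replicate 3. Its contrast was thus far smaller in mock leaves. In replicates 1 and 2 it rose with infection in WT and fell in yb2 yb3, so it is a weaker marker of genotype than the others. Every comparison that draws a direction between infected genotypes therefore rests on labels in doubt for these libraries, and each was also fitted without them. MYC2, the regulator at the head of the MYC branch of the jasmonate response, had 0 counts in all 12 libraries and gave no value in any comparison. The neighbouring gene AT1G32630 covers 98.5% of the 3289 exon bases of MYC2 on the opposite strand, so the 0 cannot be read as absence.

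**Figure D1:**
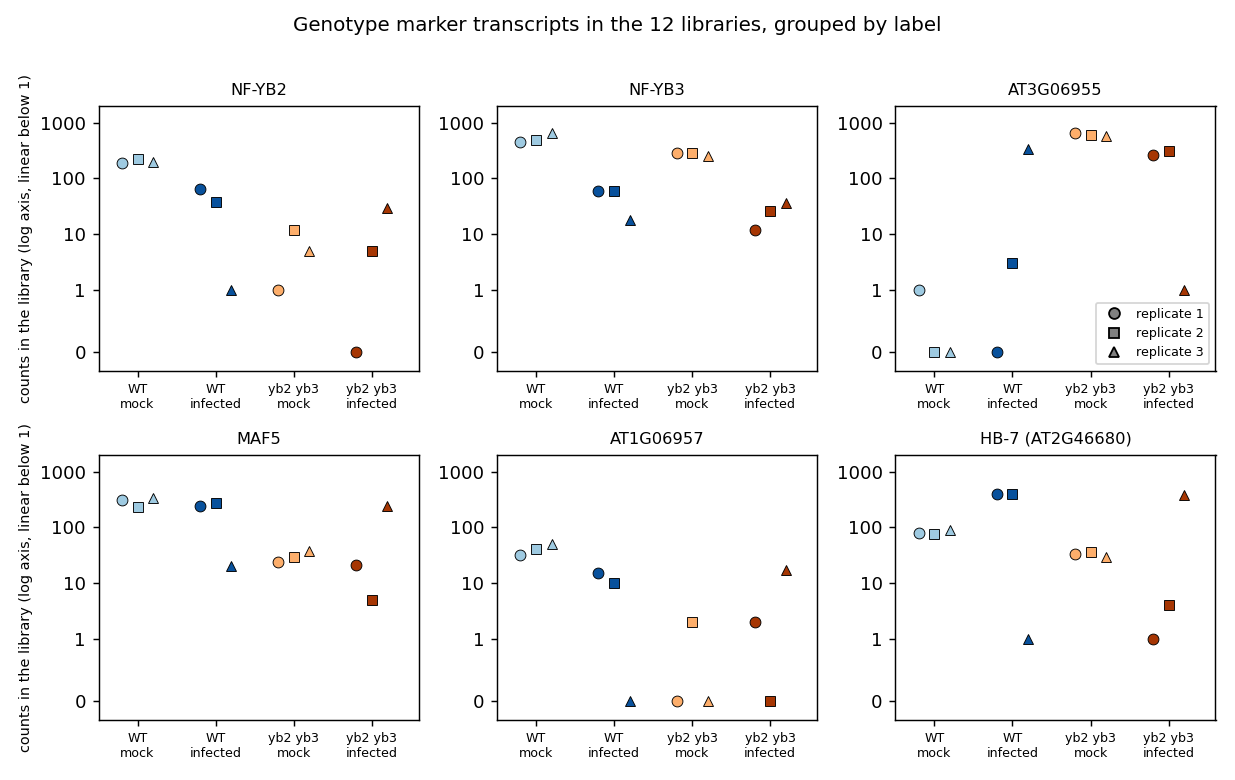
Counts per library (log axis, linear below 1) of NF-YB2, NF-YB3, AT3G06955, MAF5, AT1G06957 and HB-7 in the 4 labelled groups, with a symbol for each replicate. For AT3G06955, MAF5, AT1G06957 and HB-7 the triangles of the infected groups sit at the level of the other genotype, for example 341 counts of AT3G06955 in the library labelled WT infected replicate 3 and 1 in that labelled yb2 yb3 infected replicate 3.

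Infection of WT leaves raised antifungal defence genes of several pathways. PAD3, which makes the last step to the phytoalexin camalexin, rose from 8.77 ± 1.62 to 3284 ± 507 CPM (SD, n = 3), a log2 fold change of 8.55 (SE 0.25). The defensin PDF1.2a, a marker of joint jasmonate and ethylene signalling, rose from 19.8 ± 12.1 to 4067 ± 775 CPM (SD, n = 3; log2 fold change 7.69, SE 0.63). PR1, a marker of salicylic acid signalling, rose from 3.28 ± 1.40 to 1265 ± 173 CPM (SD, n = 3; log2 fold change 8.57, SE 0.27). The light-harvesting gene LHCB2.2 went the other way, with a log2 fold change of -6.06 (SE 0.27). For PAD3, PDF1.2a and PR1, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p of 1.99e-14, 3.41e-07 and 6.63e-14. With the same test, 14128 of 19009 genes were called, 7004 higher and 7124 lower, and 8865 of them had an absolute log2 fold change of at least 1. The group includes the library labelled WT infected replicate 3; without it and its counterpart in the mutant, 14049 genes were called, 7026 higher and 7023 lower.

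Among the largest rises in WT were genes with almost no reads in mock leaves. BGLU45, a glucosidase of lignin precursors, rose by a ratio of 6050 (95% counting interval 1080 to 239000), and CYP94B3, which inactivates jasmonoyl-isoleucine, by 2460 (441 to 97200). GulLO2, an oxidase of the family that makes ascorbate, was at least 564-fold higher, the thioredoxin TH8 at least 458-fold, the anthocyanin regulator MYB113 at least 411-fold and the wall enzyme XTH29 at least 337-fold. Among the largest falls, the germin GER3 was at least 546-fold lower, the glucanase E13L3 at least 117-fold, and the auxin-induced SAUR20 and SAUR22 at least 94.8-fold and 66.4-fold. LHCB2.3 fell from 1205 ± 122 to 1.87 ± 1.18 CPM (SD, n = 3), and the galactinol synthase GolS3 by a ratio of 658 (118 to 26000).

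Jasmonate genes rose at each level of the pathway in WT leaves. Of the biosynthesis list, 11 of 15 tested genes were higher and 3 lower, among them ACX1 (log2 fold change 3.95), OPR3 (3.17), AOC3 (5.73) and LOX2 (2.07, SE 0.22). All 8 tested catabolism genes were higher, with IAR3 at 5.97, ILL6 at 5.04 and CYP94C1 at 4.27. Of the JAZ repressors, which hold jasmonate-responsive factors inactive, 9 of 12 were higher, with JAZ1 at 5.72 and JAZ6 at 2.80. The MYC branch had 13 of 16 genes higher and 2 lower (14 higher adjusted over the list alone), with the trypsin inhibitor KTI1 at 9.66, JAV1 at 4.33 and CLH1 at 4.19, while VSP2, its storage-protein marker, stayed at low counts. VSP2 reached 1.61 CPM in infected leaves, with a log2 fold change of 2.30 (SE 0.997) and an adjusted p of 0.0503 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 16 genes of the ERF branch were higher, including ERF1 (7.12, SE 0.27), ORA59 (3.41, SE 0.22; 8.40 ± 3.26 to 88.4 ± 10.3 CPM, SD, n = 3), PDF1.2b (6.23), PR3 (8.54) and PR4 (5.52). Reads of PDF1.2a, PDF1.2b and PDF1.2c can be split between these near-identical copies, so their single values are uncertain. The medians of these lists were 2.11 for biosynthesis, 6.41 for catabolism, 4.85 for JAZ repressors (4.77 with undetected genes at their bounds), 2.80 for the MYC branch and 5.88 for the ERF branch. Camera with a preset correlation and Benjamini-Hochberg adjustment over 21 lists gave adjusted p of 0.000426, 4.81e-08, 1.4e-05, 0.000807 and 1.68e-07 for them. With the correlation within lists estimated from these libraries all 5 were lost, at adjusted p of 0.151, 0.107, 0.145, 0.159 and 0.105 by camera. In the other lists of this comparison, the counts adjusted over the list alone were the same as over all genes.

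Other defence lists rose too. All 14 genes of the camalexin and tryptophan pathway were higher in WT (median 5.27; TSA1 at 5.38), as were 10 of 11 indole glucosinolate genes (2.24; MYB122 at 8.58, CYP81F2 at 5.04) with 1 lower. Of the salicylic acid list 15 of 17 were higher and 1 lower (3.20; PBS3 at 4.42, CBP60g at 3.49), and of the ethylene list 10 of 14 were higher and 4 lower (1.15; ACS2 at 10.03, ACS6 at 5.86). Of pattern recognition genes 15 of 20 were higher and 2 lower (1.65; NHL10 at 8.79, PROPEP3 at 7.5, RBOHD at 3.42), and of WRKY factors 16 of 18 were higher and 2 lower (2.79; WRKY45 at 6.79, WRKY33 at 3.49, SE 0.15). Phenylpropanoid genes were higher in 13 of 14 (1.87; CAD5 at 5.10, PAL1 at 3.14), glutathione transferase and oxidative stress genes in 15 of 16 with 1 lower (7.06; GSTU4 at 8.77, OXI1 at 9.53), and senescence genes in 9 of 9 (2.97; SAG13 at 9.02, NYE1 at 2.97). Camera's adjusted p with Benjamini-Hochberg adjustment ran from 2.38e-17 for glutathione transferases and 1.11e-18 for camalexin to 0.00806 for ethylene. With the estimated correlation all 9 of these lists were lost, at adjusted p by camera of 0.0786 for camalexin, glutathione transferases, salicylic acid and phenylpropanoids up to 0.145 for ethylene.

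Photosynthesis and flowering genes fell in WT. All 26 photosynthesis genes were lower, with a median of -3.84; RBCS2B was at -4.45, RBCS3B at -4.62 and PSAF at -3.79, although reads of near-identical RBCS and LHCB1 copies can be split between them. Of 8 tested flowering genes 7 were lower (median -1.44), among them SVP (-1.87) and SOC1 (-2.13), and camera with Benjamini-Hochberg adjustment gave adjusted p of 1.14e-13 for photosynthesis and 0.0224 for flowering time. Both were lost with the estimated correlation, at 0.159 and 0.107 by camera. The flowering call was also lost when any of the WT infected replicates 1, 2 or 3 was left out (0.0649, 0.0794 and 0.065) and in 10 libraries (0.0668). FT itself, the mobile flowering signal, was too low to test. It had 14 counts in infected against 1 in mock leaves and was higher by a ratio of 20.2 (95% counting interval 3.07 to 853). The lists that did not pass were NF-Y (8 of 25 higher, 8 lower; adjusted p by camera 0.726), aliphatic glucosinolates (3 of 12 higher, 8 lower; MYB28 at -2.55; 0.369), cell wall (4 of 12 higher, 8 lower; XTH4 at -5.51, PGIP2 at 3.42; 0.157, but 0.0316 in 10 libraries and 0.137 there with the estimated correlation), abscisic acid response (8 of 13 higher, 5 lower; HAB1 at 1.87, RD29A at -6.49; 0.726) and circadian clock (1 of 12 higher, 7 lower; CCA1 at -2.67; 0.132). The NF-Y median was 0.02 with a mean of -0.24, and the abscisic acid median was 1.87 with a mean of -0.33. Within the NF-Y family NF-YB3 fell with a log2 fold change of -3.03 (SE 0.21) and NF-YB2 with -2.10 (SE 0.65). The NF-YB2 value includes the library labelled WT infected replicate 3, with 1 count against 65 and 38 in replicates 1 and 2. With DESeq2 NF-YB2 missed the threshold, at an adjusted p of 0.128. With the estimated correlation none of the 16 lists passed in WT, camera's adjusted p being 0.0786 to 0.159, whereas fry called 20.

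Cell type and organ markers gave a check on the tissue. Of the reference genes 4 of 6 were higher and the top member UBQ10 rose by 1.13 (SE 0.15) on the TMM-scaled library sizes, so it was no fixed standard on that scale. Infection called 74.3% of tested genes in WT, so the sizes and directions of infection changes are relative to the scaling. The 3 tested guard cell markers were lower, with AT1G22690 at -3.04 (SE 0.15), and 2 of 4 vascular markers were lower, with the phloem transporter SUC2 at -0.27 (SE 0.10). The trichome marker GL2 had a log2 fold change of -2.11 (SE 0.75) at under 1 CPM. The flower marker AG had -1.04 (SE 0.62) at under 1 CPM, with an adjusted p of 0.137 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the meristem markers only STM was read, with 1 count in mutant mock leaves, and the seed marker CRA1 had 53 counts in WT mock leaves, spread unevenly over the libraries (0.95 ± 1.59 CPM, SD, n = 3), and 0 in the other groups.

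**Figure D2:**
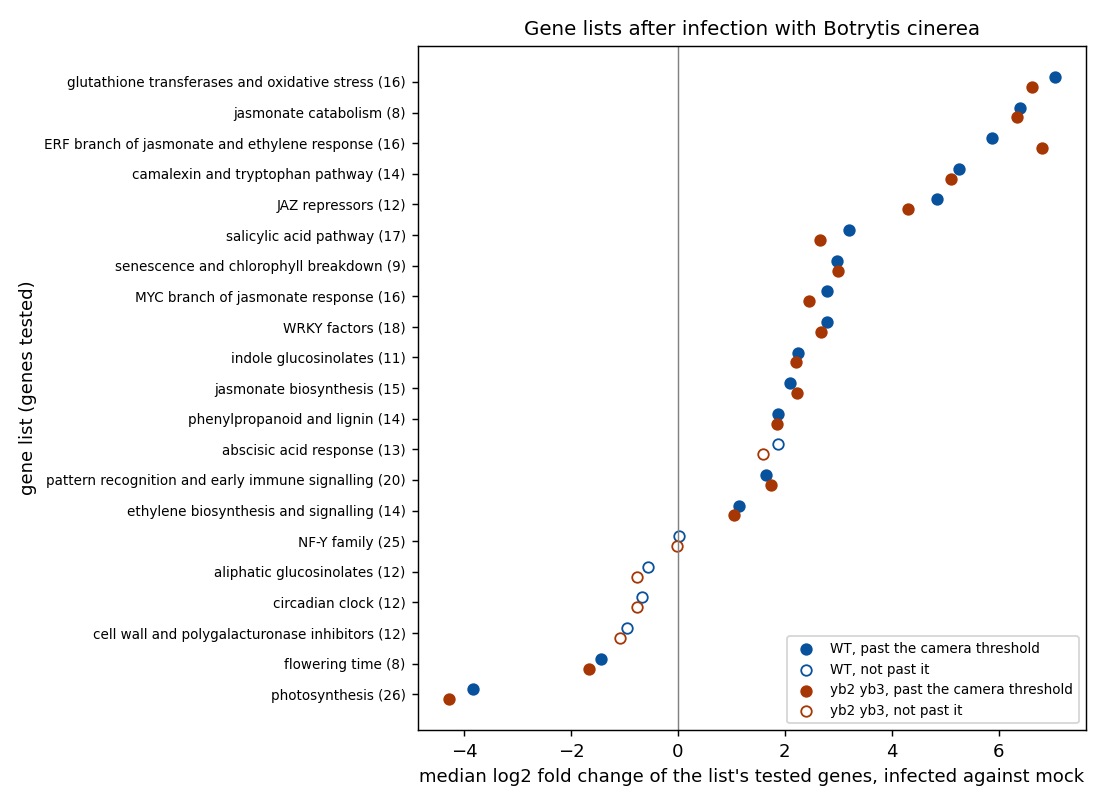
Median log2 fold change of each gene list (infected against mock; tested genes in brackets) in WT and yb2 yb3, with filled points for lists past the camera threshold. The medians ran from -3.84 for photosynthesis to 7.06 for glutathione transferases in WT, and from -4.28 to 6.81 in the mutant, where the ERF branch was highest.

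The same comparison in the mutant asked whether yb2 yb3 leaves mounted the response. PAD3 rose from 11.3 ± 2.89 to 3566 ± 416 CPM (SD, n = 3; log2 fold change 8.30, SE 0.25), PDF1.2a from 13.0 ± 9.40 to 3300 ± 681 CPM (8.00, SE 0.64) and PR1 from 2.74 ± 0.338 to 1278 ± 239 CPM (8.86, SE 0.28). ORA59 rose from 10.8 ± 1.87 to 88.2 ± 8.27 CPM (SD, n = 3; 3.03, SE 0.22), ERF1 by 7.14, PDF1.2b by 6.47, WRKY33 by 3.36 and LOX2 by 1.99 (SE 0.22). VSP2 had a log2 fold change of -0.32, with an adjusted p of 0.798 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and FT was at least 2.78-fold higher. The sign for VSP2 rests on 31 counts in yb2 yb3 mock replicate 3, against 3 and 2 in replicates 1 and 2. Without that library the value was 1.96. The edgeR test called 14339 of 19009 genes, 7012 higher and 7327 lower, with 9206 at an absolute log2 fold change of at least 1. Without the libraries in doubt it called 14309, of which 6915 were higher and 7394 lower. Scaling by library totals alone in those 10 libraries moved the median of all genes from -0.07 to -0.15 in this comparison.

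Under the naming rule the largest rises in the mutant were in CYP81G1, at least 1360-fold, PDE337, at least 1110-fold, GulLO2, at least 788-fold, and the glutathione transferase GSTU25, at a log2 fold change of 11.15 (SE 0.43). The plastid enzyme DXPS1 rose by a ratio of 2470 (95% counting interval 845 to 12000) and CYP94B3 by 3050 (546 to 120000). The expansin EXPA11 was at least 493-fold lower, MAKR1 at least 162-fold, E13L3 at least 98.9-fold, ACS4 at least 83.1-fold and the stomatal signal STOMAGEN at least 75.3-fold, and GER3 fell by a ratio of 1020 (182 to 40200). Within the NF-Y family NF-YB3 had a log2 fold change of -2.76 and NF-YB2 one of 1.56 (SE 1.16), which rests on the 29 counts in the library labelled yb2 yb3 infected replicate 3.

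Gene lists moved in the mutant as in WT, with the same 16 lists past the camera threshold. With the estimated correlation only 1 of them, salicylic acid, passed, at an adjusted p of 0.0376 by camera. The ERF branch (16 of 16 higher, median 6.81; PR3 at 8.59), jasmonate catabolism (8 of 8, 6.35), camalexin (14 of 14, 5.11; CYP71A13 at 10.31), glutathione transferases (15 of 16, 6.63; GSTU4 at 9.56) and JAZ repressors (10 of 12, 4.31; JAZ1 at 5.70) were highest. Lower medians were found for senescence (9 of 9 higher, 3.0; SAG13 at 8.46), WRKY factors (16 of 18, 2.68), salicylic acid (13 of 17, 2.66; EDS5 at 4.34), the MYC branch (11 of 16, 2.45; KTI1 at 10.61), jasmonate biosynthesis (11 of 15, 2.23; AOC3 at 6.43), indole glucosinolates (10 of 11, 2.22; MYB122 at 9.53), phenylpropanoids (14 of 14, 1.86), pattern recognition (16 of 20, 1.75) and ethylene (8 of 14, 1.06; EIL1 at -2.09). Photosynthesis fell in 26 of 26 genes (median -4.28; LHCB2.2 at -7.06, LHCB6 at -4.70) and flowering time in 7 of 8 (-1.65). The abscisic acid list again had a positive median, 1.60, and a negative mean, -0.99 (RD29A at -7.51, COR15A at -7.58), and the NF-Y median of -0.02 became 0.01 under RLE scaling. Camera's adjusted p with Benjamini-Hochberg adjustment ran from 4.88e-18 for camalexin to 0.0255 for flowering time. Adjusted over the list alone, every list of this comparison had the same counts. Flowering time was lost without yb2 yb3 infected replicate 1 (0.053) and in 10 libraries (0.0723), and the cell wall list, at 0.12 with all libraries, passed without the libraries labelled yb2 yb3 infected replicate 1, 2 or 3 (0.0275, 0.029 and 0.0207) and in 10 libraries (0.0306).

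Across 19009 genes the infection response of the mutant rose with that of WT with a Deming slope of 1.05 (jackknife SE 0.079, 1.01 to 1.1 when each library was left out) and Pearson's r of 0.968. This correlation is across genes, which are not independent replicates, and the pair of responses shares no library. Without the libraries in doubt the slope was 1.12 and r 0.952.

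**Figure D3:**
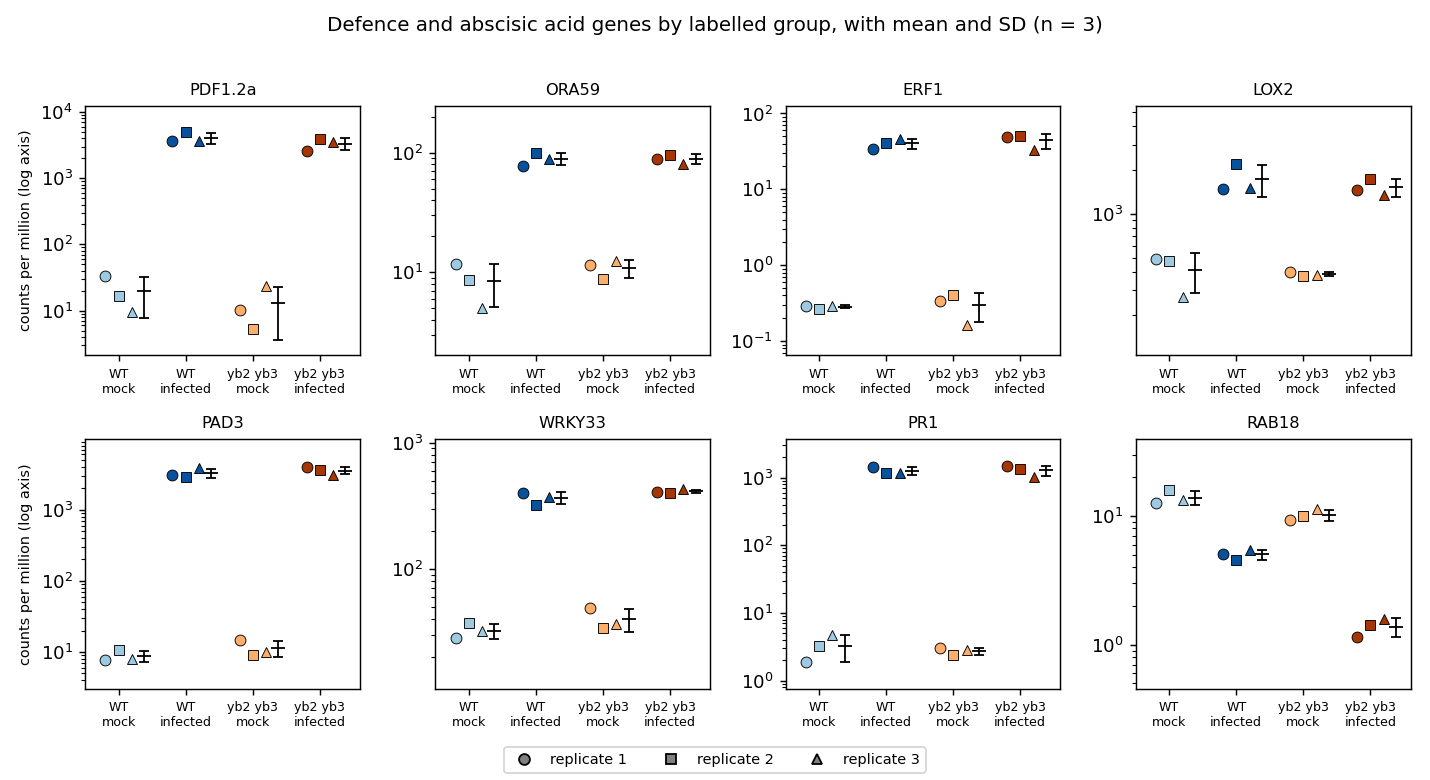
CPM (log axis) of 8 defence and abscisic acid genes in each library of the 4 labelled groups, with the mean and SD (n = 3) beside the points. PDF1.2a, ORA59, ERF1, LOX2, PAD3, WRKY33 and PR1 rose in both genotypes, while RAB18 fell to 5.02 CPM in leaves labelled WT infected and 1.38 CPM in those labelled yb2 yb3 infected.

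Comparing mock leaves of the genotypes asked what the mutations changed without the fungus, in 6 libraries where the counts of NF-YB2 matched the labels. CBF2, a factor that switches on cold-responsive genes, rose from 9.29 ± 1.95 to 26.6 ± 1.65 CPM (SD, n = 3; log2 fold change 1.52, SE 0.18), and its neighbour CBF1 by 1.49 (SE 0.25). RAP2.4, an ERF-type factor of light and ethylene responses, rose from 100.2 to 179.2 CPM (0.84, SE 0.11), the auxin-related factor MYB77 by 1.19 (SE 0.20) and the ubiquitin ligase RDUF1 by 1.04 (SE 0.16). NF-YB3 dropped from 28.0 ± 3.23 to 14.1 ± 0.550 CPM (SD, n = 3; -0.99, SE 0.17), and NF-YB2 from 10.7 ± 1.08 to 0.311 ± 0.286 CPM (-5.10, SE 0.84). The CBF genes lie side by side on chromosome 4 (CBF2 at 13015250 to 13016235, CBF1 at 13021780 to 13022996) and are similar in sequence, so reads can be split between them.

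By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p were 0.0027 for CBF2, 0.0427 for CBF1 and MYB77, 0.00461 for RAP2.4, 0.0326 for RDUF1 and 0.046 for NF-YB3, while NF-YB2, at 0.0682, missed the threshold. The test called 10 genes, 9 higher and 1 lower, against 1167 at an unadjusted p under 0.05. Without the infected libraries in doubt, which are in neither mock group but share the spread, the gene filter, the scaling and the adjustment, 158 of 19417 genes were called, 131 higher and 27 lower, and the adjusted p of NF-YB2 by the same test was 1.39e-06. After thinning these libraries to the lowest total 112 genes were called. A fit of the 6 mock libraries alone called 274, with 197 higher and 77 lower, and DESeq2 on 12 libraries called 94, with 77 higher and 17 lower. With the replicate number as a block in 12 libraries, CBF1, MYB77, RDUF1 and NF-YB3 lost their calls. Their adjusted p by edgeR's quasi-likelihood test were then 0.111, 0.113, 0.0915 and 0.123. CBF1, MYB77 and NF-YB3 lost their call when any mock library was left out, and each single omission left 0 to 6 called genes: 0 without WT mock replicate 1 or 3 or yb2 yb3 mock replicate 1, 1 without yb2 yb3 mock replicate 2, 3 without WT mock replicate 2 and 6 without yb2 yb3 mock replicate 3.

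Several factors and enzymes were among the 131 genes raised in mock mutant leaves in the 10-library fit, which were not tested as a list. ZAT10, a zinc-finger repressor of abiotic stress responses, had a log2 fold change of 2.18 (SE 0.28), the deadenylase CAF1a 1.66, the mitochondrial carrier DIC2 1.57, and the factors ERF5, ERF6 and ERF104 1.46, 1.23 and 1.12. NAC055 was at 1.25, NAC072 at 0.86, ZAT12 at 1.16, WRKY60 at 1.04, the wall enzyme XTH22 at 1.19, NIMIN1 at 2.39, the abscisic acid enzyme NCED3 at 0.81, SEN1 at 0.73 and SAG21 at 0.61. Among genes with a symbol MAF5 was the largest fall after NF-YB2, at -3.33 (SE 0.26), followed by the kinase PTI1-4 (-1.35), XTH31 (-1.02) and the glutamine synthetase GLN1;4 (-0.78). None of the jasmonate and defence genes named for every comparison differed in the 12-library fit; ORA59 was at 0.38 (SE 0.23), ERF1 at 0.11, PDF1.2a at -0.61 (SE 0.51), PDF1.2b at -0.59, VSP2 at 0.96 (-1.32 without yb2 yb3 mock replicate 3), LOX2 at -0.10, PAD3 at 0.37, WRKY33 at 0.30 and PR1 at -0.28. Their adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 0.782 for WRKY33 to 1.

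WRKY factors (median 0.27, 16 of 18 positive), senescence (0.18), ethylene (0.17) and salicylic acid (0.14) lay higher in mock mutant leaves, and photosynthesis slightly lower (median -0.09, 2 of 26 positive). No gene of these 5 lists was called over all genes; adjusted over the list alone, 3 WRKY, 4 senescence and 1 salicylic acid gene were called, and none of the ethylene and photosynthesis lists. Camera with Benjamini-Hochberg adjustment gave adjusted p of 0.000111, 0.000156, 0.00333, 0.00333 and 0.041, and with the estimated correlation all were lost, at adjusted p of 0.359 for the lists that rose and 0.714 for photosynthesis. Leaving out single libraries moved the number of lists from 5 to 11 without WT mock replicate 2 and to 2 without yb2 yb3 mock replicate 1. Photosynthesis was lost without WT mock replicate 1 or yb2 yb3 mock replicate 1 (camera's adjusted p 0.26 and 0.342), ethylene without WT mock replicate 3 or yb2 yb3 mock replicate 1 (0.0578 and 0.0828), and salicylic acid without yb2 yb3 mock replicate 1 (0.148). The ERF branch, with a median of 0.06 and a mean of -0.23, had 3 genes called adjusted over the list alone. Of the NF-Y list NF-YB3 was called over all genes, and 2 genes were called adjusted over the list alone. Guard cell markers (median -0.24, 0 of 3 positive) and vascular markers (-0.32, 2 of 4 positive, with 2 lower adjusted over the list alone) lay lower in the same mock comparison. Both were at an adjusted p of 0.0338 by camera with Benjamini-Hochberg adjustment and 0.153 with the estimated correlation, and in 10 libraries at 0.0147 and 0.0795.

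Comparing infected leaves of the genotypes addressed the series' question most directly, and by the labels few genes differed. RAB18, a dehydrin induced by abscisic acid (AT5G66400, chromosome 5, 26518277 to 26519447, minus strand), was lower in yb2 yb3, at 1.38 ± 0.225 against 5.02 ± 0.459 CPM (SD, n = 3; log2 fold change -1.82, SE 0.22). AT5G44260, a CCCH zinc-finger gene with no symbol in the annotation and chosen after its values were seen, was lower too, at 2.78 ± 0.165 against 6.58 ± 1.26 CPM (SD, n = 3; -1.21, SE 0.17). ORA59 stood at 88.2 against 88.4 CPM, PDF1.2a at a log2 difference of -0.30 (SE 0.47), PDF1.2b at -0.35, ERF1 at 0.13, LOX2 at -0.18, PAD3 at 0.12, WRKY33 at 0.17 and PR1 at 0.02, and VSP2, at low counts, at -1.67 (SE 1.02). NF-YB2, at -1.44 (SE 0.87), and NF-YB3, at -0.72 (SE 0.28), were not called either, with 1 and 29 counts of NF-YB2 in the libraries labelled WT and yb2 yb3 infected replicate 3.

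By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p were 0.00396 for RAB18 and 0.022 for AT5G44260, the only calls among 19009 genes, and from 0.706 to 0.999 for the jasmonate and defence genes just named. Unadjusted p was under 0.05 for 1556 genes. DESeq2 called 68 genes, 1 higher and 67 lower, and a fit of the infected groups alone called 0 by the edgeR test, with 798 at an unadjusted p under 0.05. Leaving out the library labelled WT infected replicate 3 raised the calls to 393, and leaving out the one labelled yb2 yb3 infected replicate 3 raised them to 12. AT5G44260 lost its call by that test without WT infected replicate 2 or yb2 yb3 infected replicate 1 or 2, at adjusted p of 0.0651, 0.154 and 0.115, and with the replicate block (0.0657). In the fit of the infected groups alone neither gene was called, and RAB18 had no adjusted value from DESeq2.

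Without the libraries labelled WT infected replicate 3 and yb2 yb3 infected replicate 3, 1358 of 19417 genes were called, 533 higher and 825 lower in the mutant. Scaling by library totals alone gave 1409, 314 higher and 1095 lower, so the balance of directions depended on the scaling; the median of all genes moved from -0.03 to -0.10. ORA47, a factor that switches on jasmonate biosynthesis, was higher, at 12.2 against 3.28 CPM (log2 fold change 1.88, SE 0.22, n = 2), as were BT5 (1.92, SE 0.18), the small heat-shock protein HSP18.2 (2.08, SE 0.47), OXS3 (1.39), DIC2 (1.38) and PHI-1 (1.37). The abscisic acid and drought gene RD22 was lower, at 5.57 against 33.9 CPM (-2.58, SE 0.31, n = 2), as were MAF5 (-3.76), the lipid transfer protein LP1 (-2.70), the wall protein PRP4 (-2.59), SPL13A (-2.25) and KCS8 (-1.74). NF-YB2 was at -3.77 (SE 0.69) and NF-YB3 at -1.09 (SE 0.29), and RAB18 stayed low at -1.90 (SE 0.30), as did AT5G44260 at -1.11. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p were 3.36e-05 for ORA47, 7.04e-06 for BT5, 0.00127 for RD22, 0.00422 for NF-YB2, 0.0228 for NF-YB3, 0.000774 for RAB18 and 0.00459 for AT5G44260. Each group then held 2 libraries, and of the 9 ways to leave out 1 infected library from each group this was the one with the most calls, the next being 385 and 171 where the library labelled WT infected replicate 3 was out together with yb2 yb3 infected replicate 2 or 1.

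In those 10 libraries some jasmonate genes were higher in infected mutant leaves, while the biosynthesis list, with a median of 0.11 and 2 of 15 genes called, did not pass (camera's adjusted p 0.139). Of the JAZ repressors 5 of 12 were higher (JAZ7 at 1.16, JAZ8 at 0.73, JAZ10 at 0.74, JAZ5 at 0.53) and of the catabolism genes 4 of 9 (JOX3 at 0.71, JOX4 at 0.72, ILL6 at 0.45, CYP94B3 at 0.57). In the MYC branch NAC055 and NAC072 were each at 1.09, NAC019 at 0.82 and KTI1 at 0.69, and in the ERF branch ERF104 was at 1.31, ERF6 at 1.01 and ERF5 at 0.86, whereas PDF1.2a, at -0.42 (SE 0.70), PDF1.2b, at -0.51, ORA59, at 0.07, and ERF1, at 0.41, were not called. Single genes of other lists moved the same way, among them AOC3 (0.58), ACS2 (0.57), ACS6 (0.49), CYP82C2 (0.75), CYP81F2 (0.53), PROPEP1 (0.95), WRKY29 (1.16) and CCR2 (0.999), while PR5 (-0.49), the flagellin receptor FLS2 (-0.59), EIL1 (-0.46), CESA4 (-1.15) and RD29A (-1.24) were lower. EXPA8, an expansin, was lower by a ratio of 40.9 (95% counting interval 7.06 to 1640). Of the photosynthesis genes 25 of 26 were lower, with LHCB1.1 at -1.52, LHCB2.2 at -1.39, LHCB2.1 at -1.37 and SBPASE at -0.87. PAD3 (0.34), WRKY33 (0.16), PR1 (0.10), LOX2 (-0.20) and VSP2 (-1.17) were not called. Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.0677 for ERF1, 0.799 for PDF1.2a and 0.288 for PAD3.

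Lists tested between infected genotypes moved little in the 12-library fit. Photosynthesis had a median of -0.60 with 26 of 26 genes negative, none called over all genes and 20 adjusted over the list alone, and WRKY factors had a median of 0.25 with 17 of 18 positive, 0 called over all genes and 1 adjusted over the list alone. Jasmonate catabolism (0.22), JAZ repressors (0.21), indole glucosinolates (0.14) and camalexin (0.10) lay just past the threshold with no called gene, all at an adjusted p of 0.0497 by camera with Benjamini-Hochberg adjustment, beside 1.27e-23 for photosynthesis and 3.7e-05 for WRKY factors. With the estimated correlation none passed, the adjusted p being 0.462 for photosynthesis and WRKY factors and 0.734 for the other lists. The 4 lists at 0.0497 were lost when any of the infected replicates 1 and 2 of either genotype was left out, with camera's adjusted p at 0.0673 to 0.731. Guard cell markers lay lower as well, with a median of -0.46. Adjusted over the tested marker lists alone, their p by camera was 0.0183, 0.176 with the estimated correlation and 0.125 in 10 libraries. Their median there was larger, at -0.60. In 10 libraries 11 lists passed the preset test, with medians of -0.92 for photosynthesis, 0.55 for catabolism, 0.39 for JAZ repressors, 0.33 for senescence, 0.31 for camalexin, 0.28 for glutathione transferases, 0.28 for WRKY factors, 0.25 for the MYC branch, 0.20 for indole glucosinolates, 0.17 for the ERF branch and 0.10 for phenylpropanoids. With the estimated correlation none of the 11 passed, with camera's adjusted p at 0.196 for JAZ repressors, 0.213 for photosynthesis and catabolism, and up to 0.426. Adjusted over the list alone, 6 genes each of the catabolism, JAZ and ERF lists were higher and all 26 photosynthesis genes lower.

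The interaction tested whether the mutant's response to infection differed from that of WT. AT5G44260 was called, with a log2 difference in response of -1.85 (SE 0.20): it fell from 56.7 ± 2.65 to 6.58 ± 1.26 CPM in WT and from 88.4 ± 8.97 to 2.78 ± 0.165 CPM in the mutant (SD, n = 3). No jasmonate or defence gene named for every comparison was called, with differences in response of -0.38 (SE 0.30) for ORA59, 0.02 for ERF1, 0.31 (SE 0.69) for PDF1.2a, 0.24 for PDF1.2b, -2.63 (SE 1.47) for VSP2 (-0.34 without yb2 yb3 mock replicate 3), -0.08 for LOX2, -0.25 (SE 0.27) for PAD3, -0.13 for WRKY33 and 0.29 for PR1. NF-YB2 was at 3.66 (SE 1.33), a value that rests on the 29 counts in the library labelled yb2 yb3 infected replicate 3 and the 1 in that labelled WT infected replicate 3, and NF-YB3 was at 0.27. Without these libraries they were at 1.33 (SE 1.15) and -0.10. AT5G44260 was then at -1.75 (SE 0.23), ORA59 at -0.31, ERF1 at 0.31, PDF1.2a at 0.18, PDF1.2b at 0.08, VSP2 at -2.12 (SE 1.66), LOX2 at -0.10, PAD3 at -0.03, WRKY33 at -0.14 and PR1 at 0.38. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.001 for AT5G44260 and from 0.883 to 1 for the jasmonate and defence genes, and in 10 libraries 0.00057 and from 0.65 to 1. AT5G44260 was the only call of 19009, against 1146 at an unadjusted p under 0.05, while DESeq2 called 20 genes. Leaving out the library labelled WT infected replicate 3 gave 9 calls and leaving out the one labelled yb2 yb3 infected replicate 3 gave 4.

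Without both libraries in doubt, 167 genes differed in response, 31 with a higher and 136 with a lower value in the mutant. After thinning every library to the lowest total 104 genes did. With scaling by library totals alone 359 did, 24 higher and 335 lower, with the median of all genes moving from -0.05 to -0.16. Among called genes under the naming rule, MAPKKK19 (2.43, SE 0.45), UGT73C7 (2.0), the NADPH oxidase RHD2 (1.93), NAXT1 (1.66), ORA47 (1.15, SE 0.27) and BT5 (1.11) had the largest positive differences. The largest negative ones under that rule were in CAD9 (-5.84), EXPA8 (-4.96), XTH29 (-4.67), BZIP34 (-3.90), GRP5 (-3.86) and DRT100 (-3.32), values that depend on 0 to 4 counts in 1 group and bound nothing. HB-7, carried under its locus code AT2G46680, was outside the rule and not ranked. RD22 (-2.60, SE 0.36), RD29A (-1.66), RAB18 (-1.45), EIL1 (-0.67), LHCB1.1 (-1.40), LHCB2.2 (-1.36) and LHCB2.1 (-1.23) fell further in the mutant. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.0124 for RD22 and LHCB2.2, 0.04 for RAB18 and 0.0468 for ORA47.

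In the 12-library fit the abscisic acid list, with a median difference in response of -0.65, and the photosynthesis list, at -0.44, passed the preset camera test with Benjamini-Hochberg adjustment, at adjusted p of 0.00522 and 1.34e-08. Neither passed with the estimated correlation (adjusted p 0.215 and 0.85), no photosynthesis gene was called adjusted over the list alone, and 1 abscisic acid gene was. Without the library labelled WT infected replicate 3 the abscisic acid list was lost, with camera's adjusted p at 0.132, and without both libraries in doubt it was lost too, with a median of -0.29 and camera's adjusted p at 0.0612. In 10 libraries photosynthesis had a median of -0.84, with 3 of 26 genes called and 21 adjusted over the list alone, jasmonate catabolism one of 0.61, JAZ repressors one of 0.24 and camalexin one of 0.21. Their adjusted p by camera with Benjamini-Hochberg adjustment were 3.83e-25, 0.00454, 0.0446 and 0.0132, and with the estimated correlation 0.49, 0.49, 0.501 and 0.735.

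**Figure D4:**
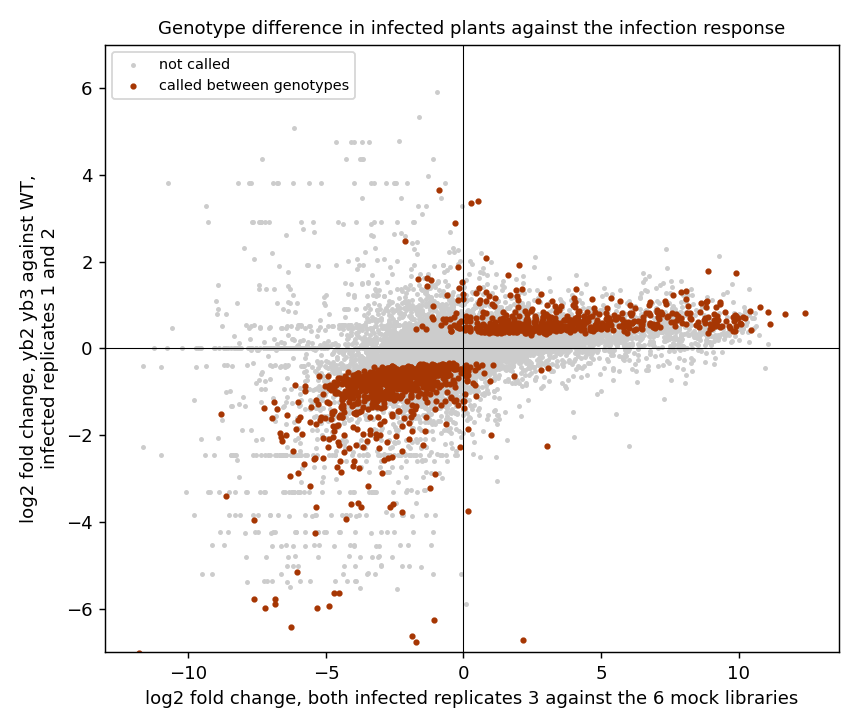
Log2 fold change of yb2 yb3 against WT in infected replicates 1 and 2 plotted against the log2 fold change of both infected replicates 3 over the 6 mock libraries, for 19126 genes, with the 1357 called genes in brown. Called genes lie mostly in the lower left and upper right, with the same sign on both axes in 1291 of them; 2 points lie outside the plotted range.

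Genes that differed between infected genotypes were set against the infection calls in WT. In 12 libraries both genotype calls, RAB18 and AT5G44260, also fell with infection in WT, and r between the fold changes across 19009 genes was 0.216 with a covariance of 0.249. In 10 libraries 1292 genes were called in both comparisons: 470 rose with infection and were higher in the mutant, 757 fell and were lower, 31 rose and were lower and 34 fell and were higher. Independent lists of these sizes would share 192.9, 298.4, 298.5 and 192.8 genes in these classes. The correlation was 0.304 and the covariance 0.521. The comparisons share the WT infected libraries, which pushes them towards opposite signs: in 5 simulations of unchanged groups the mean overlap was 0, r was -0.519 in 12 and -0.522 in 10 libraries, and the covariance was -0.067 and -0.105. Unchanged groups give hardly any calls, so the simulated overlap of 0 is no measure for the 1292 genes. The simulated r comes from the spread alone, so only the covariances were compared. The covariance observed was above the simulated one by 0.316 and 0.626. The WT infected libraries were too few to split. Against a response measured in both infected replicates 3, which shares no library with the 10-library genotype comparison, r was 0.674 over 1357 called genes, with the same sign in 1291.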

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

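Chosen after the result was seen were the fits of 10 libraries, the splits of the mock and of the infected libraries between genotypes, the tests of RNA mixing, of progress of infection and of uneven inoculation, and both tests of the mock difference (hour of harvest, handling). A direction drawn between infected genotypes rests on labels in doubt for the libraries labelled WT infected replicate 3 and yb2 yb3 infected replicate 3. The test of an exchange of labels, the response outside the comparison and the thinning use these libraries or leave them out. They were thus set after these libraries had stood out.

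AT5G44260, a zinc-finger gene, stood out because its infection response differed between the genotypes by the interaction test, with a log2 difference of -1.85 (SE 0.20). It was higher in mutant than WT mock leaves, by 0.64, and lower in infected ones, by -1.21. The abscisic acid response list (median difference in response -0.65) and the photosynthesis list (-0.44) stood out by the same contrast in the preset camera test with Benjamini-Hochberg adjustment, at adjusted p of 0.00522 and 1.34e-08. Neither passed with the estimated correlation (0.215 and 0.85) or by fry (adjusted p 0.0988 and 0.902), and the abscisic acid list was lost without the library labelled WT infected replicate 3, with camera's adjusted p at 0.132, and in 10 libraries, at 0.0612 with a median of -0.29. Of 50 draws with genotypes permuted within treatments, 8, the real grouping included, gave at least its 1 call, so chance cannot be excluded for that count, which does not test AT5G44260 itself. That gene kept its call in the interaction without each of the 12 libraries in turn and in 10 libraries, but not with limma voom (adjusted p 0.074). The highest other draw called 90 genes. The 5 draws with more calls than the real one (90, 83, 22, 14 and 8) all set WT infected replicates 1 and 2 with the library labelled yb2 yb3 infected replicate 3 against the other infected libraries, which points to a structure of the samples that the labels do not give.

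In splits of 3 libraries against 3 there are 10 groupings, too few for a share under 0.05. Infection in WT called 13485 genes in the real split and 0 in the highest other, infection in the mutant 14005 and 0, and genotype in mock leaves 274 and 0; in each, 1 of 10 splits reached the real count. Between infected genotypes the real split called 0 genes by edgeR's quasi-likelihood test, with 798 at an unadjusted p under 0.05, so that all 10 splits reached it, and the highest other called 567. That split exchanges the libraries labelled WT infected replicate 3 and yb2 yb3 infected replicate 3, and no other split called more than 2, which points to a structure of the samples.

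The pattern behind this is that these libraries carry most genotype markers of the other group, as with 341 and 1 counts of AT3G06955, though NF-YB3 in the library labelled yb2 yb3 infected replicate 3, at 2.38 CPM, was near replicate 2 of its label, at 2.46. An exchange of their labels needs all infected libraries to deviate over genes that differ between mock genotypes in fixed directions, and 6 of 6 did (266 genes, the 8 strongest left out; correlations -0.532, -0.536 and 0.451 in WT replicates 1, 2 and 3, and 0.415, 0.371 and -0.262 in the mutant). Mixing of RNA or reads is argued against by 6 markers, whose share with the labelled genotype's profile was at most 4% (95% upper limit, the higher of both libraries). For 8 markers a different progress of infection is argued against by a ratio of 0.244, since infection moved them by a median of 0.91 where they deviated by 3.74. These 8 were selected for an absolute log2 fold change of at least 2 between mock genotypes, so the ratio does not speak for other genes. Of the 1357 genes called in replicates 1 and 2, 1107 (81.6%) had the opposite sign between the replicates labelled 3 and 250 the same sign. Most of these genes also followed the infection response, so a difference in progress of infection could give opposite signs as well. Along that response the libraries labelled WT and yb2 yb3 infected replicate 3 lay at 0.976 and 0.92, though both were used to define it. An exchange of labels is a candidate explanation for most of the marker values, and for the other genes progress of infection stays possible beside it. No library was relabelled.

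A second pattern concerns the 10-library fit, where yb2 yb3 differences in infected leaves followed the infection response: LHCB2.2 and RD22, which infection lowers, were lower still, and JAZ8 and CYP94B3, which it raises, were higher. A position further along one common response is one possible explanation, since over 1357 called genes the differences correlated at r of 0.674 with a response measured in libraries outside the comparison, and 1291 (95.1%) had its sign; r over all 19126 genes was 0.409, and r squared over the called genes was 45.4%. Lower depth of the mutant libraries is argued against, as thinning every library to the lowest total gave 1445 calls against 1358, with 1217 shared, though the interaction calls fell from 167 to 104. Positions along the response were 0.866 and 0.833 in WT infected replicates 1 and 2 and 0.998 and 0.925 in those of the mutant, and an exact permutation test of 2 libraries against 2 cannot go below a two-sided p of 0.333. Uneven inoculation or timing between plants and an effect of the mutations cannot be told apart here, because no label gives lesion size, dose per leaf or time.

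The third pattern is the 9 genes called higher in mock mutant leaves, among them CBF2, CBF1, RDUF1 and RAP2.4, which were not tested as a list. For a different hour of harvest, 12 clock genes differed by a median of 0.08 (at most 0.60), 0.069 of the median rise of 1.15 in the 9 raised genes. These 9 were selected for being called higher, which makes the ratio low in advance, so the ratio cannot decide. The clock median by itself argues only against a difference in hour large enough to shift most of these clock genes. Handling at harvest cannot be told apart from genotype, because mock plants of a genotype may have been handled together. Of 131 genes raised in mock mutant leaves in the 10-library fit, 92.4% had the same sign in infected leaves, with median differences of 0.78 and 0.49. Of the 27 lowered genes, 21 had the same sign. No share over all genes was computed beside these, and the infected mutant libraries of that fit also lay further along the infection response. Across genes r was 0.71 over the called genes but 0.114 over all. Of the 9, AT5G44260 (-1.11), PNP-A (-0.41) and AT4G18253 (-0.21), chosen after their values were seen, were lower in infected mutant leaves. An effect of the mutations stays open, as does a change in tissue make-up, which was not tested as an explanation.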

How the results depend on the processing

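The fits without both libraries in doubt (10 libraries), alone or with DESeq2, library totals, the replicate block or an estimated correlation, were chosen after the result was seen; the other alternatives were planned.

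Infection calls kept within 1.5 times their count under every alternative but a demand of 1 on the absolute log2 fold change, which left 8865 genes in WT and 9206 in the mutant; that demand itself removes the smaller changes. The slope stayed between 1.01 and 1.12.

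Genotype calls in mock leaves (10 genes) became 94 with DESeq2, 39 with library totals, 31 without a filter, 6 with a filter of 10 CPM, 2 with the replicate block, 274 in a fit of the mock groups alone, 22 with limma voom, and 6 with an absolute log2 fold change of at least 1. With 10 libraries they were 158, and 186 with DESeq2, 159 with library totals and 204 with the block. Leaving out single libraries gave 0 to 6 (0 without WT mock replicate 1 or 3 or yb2 yb3 mock replicate 1, 1 without yb2 yb3 mock replicate 2). Calls by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were lost for CBF2 without WT mock replicate 1 or 3 or yb2 yb3 mock replicate 1 (adjusted p 0.0851, 0.0741 and 0.0623), and for RAP2.4 without those or yb2 yb3 mock replicate 2 (0.128, 0.0741, 0.0777 and 0.0761). NF-YB3 was lost with totals (0.0561), the block (0.123) and each library left out (0.0648 to 0.373), as were CBF1 and MYB77 under the block and each omission (0.0509 to 0.373), and RDUF1 under the block and every omission but yb2 yb3 mock replicate 3 (0.0509 to 0.363). NF-YB2 passed with DESeq2 (adjusted p 0.0322) and totals (0.0497) and in 10 libraries (1.39e-06). Beyond fewer or more libraries the cause was not tested.

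Genotype calls in infected leaves (2 genes) became 68 with DESeq2, 10 without a filter, 0 in a fit of the infected groups alone (798 at an unadjusted p under 0.05) and 0 with limma voom (1476). Leaving out single libraries gave 1 to 393: 393 without the library labelled WT infected replicate 3, 12 without the one labelled yb2 yb3 infected replicate 3, and 1 without WT infected replicate 2 or yb2 yb3 infected replicate 1 or 2. With 10 libraries there were 1358, with DESeq2 1375, with totals 1409 and with the block 1606. NF-YB3 passed without the library labelled WT infected replicate 3 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0.0463). On simulated data an exchange of 2 infected libraries left 0 of the planted genes recovered, so the labels in doubt alone can remove calls.

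Calls of the interaction (1 gene) became 20 with DESeq2, 2 with RLE factors, 2 without a filter and 0 with limma voom (1006 at an unadjusted p under 0.05), and 1 to 9 without single libraries (9 without the library labelled WT infected replicate 3, 4 without yb2 yb3 infected replicate 3). With 10 libraries they were 167, with DESeq2 325, with totals 359 and with the block 277. The overlap of 2 genes became 66 with DESeq2, 1 with the block, 1292 in 10 libraries and 1311 there with DESeq2; the cause was not tested beyond the libraries left out.

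Lists past camera fell from 16 to 0 (WT infection) and 1 (mutant infection) with the estimated correlation, and to 3 and 5 with it in 10 libraries. For genotype in mock leaves 5 became 0 with the estimated correlation, 0 with fry, 8 in 10 libraries, 10 there with the block, 0 there with the estimated correlation, and 2 to 11 without single libraries. For genotype in infected leaves 6 became 0, 0 with fry, 2 with the block (the other 4 at an adjusted p by camera of 0.0713), 11 in 10 libraries, 11 there with the block, 0 there with the estimated correlation, and 2 to 10 without single libraries: 3 without WT infected replicate 1 or 2, 2 without yb2 yb3 infected replicate 1 or 2 and 10 without the library labelled yb2 yb3 infected replicate 3. For the interaction 2 became 0, 0 with fry, 4 in 10 libraries, 4 there with the block, 0 there with the estimated correlation, and 2 to 6 without single libraries (4 without WT mock replicate 3, yb2 yb3 mock replicate 3 or yb2 yb3 infected replicate 3, 5 without yb2 yb3 infected replicate 1, 6 without WT infected replicate 2).

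Same-numbered replicates did not deviate together: their correlations were -0.251 to 0.082 over 18 pairs, with 0 over 0.1, and 2 of 12 libraries were closest to their own number. The numbers were not read as pairs.

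Of 2472 values of named genes under alternatives, 2390 kept their direction and side of the threshold, 36 fell short of it and 11 newly passed it. Another 35 changed sign with neither fit past the threshold, and 0 changed sign with a fit past it. Most of the 2472 values belong to the infection comparisons, and values without an adjusted p were left out. Of the 36, 30 came from the mock genotype comparison with single libraries left out, among 96 values, and 4 from its replicate block. VSP2 passed for WT infection with DESeq2, totals and the block and without WT mock replicate 2 or WT infected replicate 1 (adjusted p 0.0174 to 0.0479 by these fits with Benjamini-Hochberg adjustment), and NF-YB2 there missed it with DESeq2 (0.128). Depth limits genes under about 0.143 to 0.315 CPM, the limits of 3 counts, among them FT in mock leaves and most flower and seed markers. In WT infected replicates 1 and 2 FT was above these limits, at 0.447 and 0.427 CPM.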

Other observations

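Families of genes picked by words in their product description were tested as an exploratory set of 17; no test in this part was chosen after the result was seen except the fits of 10 libraries and the values of RAB18 and AT5G44260 per library. Of glutathione S-transferase genes 35 of 46 rose and 9 fell with infection in WT (median log2 fold change 2.71), and 32 rose and 9 fell in the mutant (2.67). NAC domain genes rose in 37 of 52 and fell in 4 (1.71), and expansins fell in 13 of 16 and rose in 2 (-3.63), with medians of 1.76 and -3.75 in the mutant. Aquaporins fell in 14 of 24 and rose in 6 (-1.62), auxin-related genes fell in 67 of 105 and rose in 27 (-1.28), tubulins fell in 21 of 28 and rose in 3 (-1.34), and heat shock genes rose in 53 of 89 and fell in 18 (0.55). Camera with Benjamini-Hochberg adjustment over the 17 families gave adjusted p in WT of 1.92e-12 for glutathione S-transferases, 2.89e-07 for NAC, 0.000533 for expansins and aquaporins, 0.00444 for auxin, 8.66e-06 for tubulins and 0.000125 for heat shock genes. With the estimated correlation none of the 17 passed in WT, with adjusted p of 0.0942 for glutathione S-transferases, and in the mutant glutathione S-transferases and pectin-related genes did, each at 0.04.

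Between mock genotypes the family named ethylene response factor had a median of 0.28 with 15 of 17 genes positive and none called over all genes, while 6 were called adjusted over the list alone; camera with Benjamini-Hochberg adjustment gave an adjusted p of 1.76e-08, and with the estimated correlation 0.215. Ribosomal protein genes lay slightly lower, at a median of -0.08 over 308 genes (adjusted p by camera 8.51e-07, with the estimated correlation 0.809). With infection in WT the ribosomal median was 0.24 and the mean -0.11, and camera's adjusted p was 0.875.

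RAB18 had 5.05, 4.55 and 5.47 CPM in the libraries labelled WT infected replicates 1, 2 and 3, and 1.14, 1.42 and 1.59 CPM in those labelled yb2 yb3 infected, so it followed the labels in all 6, as the test that called it by label selects for. AT5G44260 did so as well, with 5.56, 6.19 and 7.99 CPM against 2.59, 2.84 and 2.91 CPM. Both are among the 250 of 1357 genes whose difference had the same sign in replicates 3 as in replicates 1 and 2. In mock leaves RAB18 had 12.6, 15.8 and 13.2 CPM in WT and 9.32, 9.94 and 11.3 CPM in the mutant.

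Besides MYC2, NF-YC2, SPL3 and PGIP1 had 0 counts in all libraries, with 99.7%, 97.3% and 92.6% of their exon bases shared with a gene on the opposite strand. CCR1 (77.2% shared) had 3189 counts in total and FLC (68.1%) had 107, and these values are uncertain for the same reason.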
